A study of Homo sapiens with 4 samples.

How the data were processed

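RNA from the uveal melanoma cell line 92.1 was sequenced in 4 libraries, 2 from parental cells and 2 from a resistant derivative of the line. Per the labels' protocols, RNA was extracted with a phenol-based reagent, messenger RNA was enriched by poly(A) selection or ribosomal RNA was depleted, and stranded libraries were made by a dUTP method. Both enrichment routes are named, and which one applied to which library is not given in the sources used here. The cell line label counts up by 1 from sample to sample, while the titles name 92.1 for all 4, and all were treated as 92.1 after the titles. The labels call the second group resistant without naming the agent. Nothing in them says whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

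Per the file headers, the deposited values are FPKM (fragments mapped to a gene, scaled to transcript length and to the library's mapped fragments), with 1 value per gene and library. Per the submitters' processing notes the genome build was hg38. The aligner, the program that computed FPKM, the annotation release and any use of strand in counting are not given in the sources used here. Of the 11650 gene identifiers in each file, 11551 carry the kind of suffix that GENCODE adds to annotation mapped onto the older human build, so the annotation behind the values was not settled. The smallest value of the larger group mean was 0.5009 FPKM, so a minimum of about 0.5 on that mean seems to have been applied before deposit, and genes below it were not analysed here. Of the genes, 11596 were found by identifier in GENCODE release 29 on GRCh38, and 11585 are protein-coding there. Symbols came from a table of current gene names and from that release. Positions are those of release 29.

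FPKM values are not read counts, so no count model was used. Depth could only be guessed at from low values. In genes with 1 annotated transcript and a value below 0.6 FPKM x kb, the fullest window of 1% width held 5, 4, 3 and 4 genes, and if it marked 1 fragment the libraries held 10500000 and 13100000 (parental) and 7100000 and 4600000 (resistant) fragments. Other windows held as many genes in 3 of the libraries, so these depths are weak hints and no interval was drawn from them. An exact 0 may be a failed estimate, and such a gene is described as listed at 0.

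Values were transformed as log2(FPKM + 1) with no further scaling. Genes with a mean of at least 1 FPKM over the 4 libraries were tested (10271 genes). This filter and the apparent deposited minimum can both pass a gene that is low in 1 group through its level in the other. Resistant libraries were compared with parental libraries in limma 3.58.1 under R 4.3.3, with a variance trend, two-sided, and Benjamini-Hochberg adjustment over all genes tested at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so calls rest on the spread that limma shares between genes. Tables and figures were made in Python 3.11.15.

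A total of 40 gene lists (pathways, lineage markers, markers of other cell types and library checks) were fixed before the data were examined, as were the tests and the alternatives except where stated. List members without a value or below the filter were left out, so a list's result covers only its tested members. The 39 lists with at least 3 tested members were tested with limma camera at a preset inter-gene correlation of 0.01, with adjustment over lists. Chromosomes with at least 50 tested genes were tested in the same way. Camera compares a list with all other genes, whose median log2 fold change was -0.079. For each list, members were also adjusted over the list alone. That adjustment was not corrected for the number of lists, so a member that passed it alone is not a call over all genes.

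Genes were named by a fixed rule. It took up to 12 genes in each direction with the largest log2 fold change among those past the threshold with groups that did not overlap, up to 4 members past the threshold in the direction of each list that passed, up to 2 such members of each other list, up to 2 members of highest mean FPKM where a list had none past it, and 13 genes of lineage and line identity. No list member passed the adjustment over all genes. Members of lists that passed the adjustment over the list alone, and any other gene outside the rule, were chosen for naming after their values were seen. PRAME, ABCB1 and ABCG2, which belong to the rule, had no FPKM value in either group and so were not analysed here.

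On simulated data with the real means and 200 changed genes, the gene test recovered 17.1% of 2-fold and 90.7% of 4-fold changes, with 4.5% false calls among all calls. The list test gave p under 0.05 for 4.0% of 200 unchanged simulated lists, and found 10 of 10 lists shifted by 0.5 on the log2 scale. The changed genes were drawn only from genes above about 4 FPKM. Simulated genes varied independently of each other and with the same spread in both groups. In the list simulation, genes of the same mean also had the same spread. These rates therefore do not cover changes of lower genes, lists whose members vary together, or a larger spread in the resistant libraries. The alternatives were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, rescaling each library to a common sum, median-of-ratios scaling, quantile normalization, the replicate number as a block, no variance trend, a test against a fold change of 1.5, an estimated inter-gene correlation and each library left out in turn. The common sum was larger than the deposited sums, so the pseudocount of 1 weighed less there. Robust variance moderation, library weights, leaving out the mitochondrially encoded genes and a threshold of 0.1 were added after seeing the data. With 1 library left in a group, that library is assumed to vary like those of the other group.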

Results

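The transcriptome of 92.1, an established line of uveal melanoma (a tumour of pigment cells of the eye), was measured by RNA sequencing in 2 parental and 2 resistant libraries. The comparison asks which transcripts differ between the parental line and its resistant derivative. The sum of FPKM was 282602 and 283387 in the parental libraries and 292736 and 293481 in the resistant libraries. True depth is unknown. Log2 values correlated across genes at 0.971 between the parental libraries and 0.945 between the resistant libraries, and at 0.925 to 0.952 between groups. The pooled SD between replicates was 0.266 on the log2 scale in parental and 0.378 in resistant libraries.

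Resistant libraries held far more mRNA of CRYAB, HTN1, HTN3, SFRP1 and TMSB4X, and far less of NMRK2. CRYAB, which encodes the small heat shock protein alpha B-crystallin, rose from 3.19 ± 1.58 FPKM (SD, n = 2) in parental to 89.1 ± 0.607 FPKM (SD, n = 2) in resistant libraries. SFRP1, which encodes a secreted antagonist of Wnt signalling, rose from 22.3 ± 0.569 to 133 ± 1.69 FPKM (SD, n = 2 each). NMRK2, which encodes a nicotinamide riboside kinase of the NAD salvage route, fell from 158 ± 11.2 to 14.1 ± 0.309 FPKM (SD, n = 2 each). These were the 6 genes past the threshold, 5 higher and 1 lower in resistant cells.

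HTN1 and HTN3 encode histatins, small histidine-rich peptides known from saliva. HTN1 stood at 0.338 and 0.425 FPKM in the parental libraries and at 24.6 and 26.6 FPKM in the resistant libraries. HTN3 stood at 0.0345 FPKM in one parental library, was listed at 0 in the other, and stood at 12.3 and 12.4 FPKM in the resistant libraries. The pair are close paralogs, so the division of reads between them is uncertain. Their summed FPKM was 0.372 and 0.425 in parental and 36.9 and 39 in resistant libraries. TMSB4X, which encodes the actin-binding peptide thymosin beta 4, rose from 1.11 ± 0.311 to 13.4 ± 1.11 FPKM (SD, n = 2 each). It has many processed copies in the genome, so its level is uncertain too.

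In limma, CRYAB changed by 4.48 ± 0.29 (log2 fold change ± SE, adjusted p = 0.0268), HTN1 by 4.27 ± 0.18 (adjusted p = 0.00724) and HTN3 by 3.72 ± 0.17 (adjusted p = 0.00724). TMSB4X changed by 2.77 ± 0.20 (limma adjusted p = 0.0424), SFRP1 by 2.53 ± 0.14 (limma adjusted p = 0.0168) and NMRK2 by -3.40 ± 0.15 (limma adjusted p = 0.00724). With a pseudocount of 0.1 the log2 fold change was 6.75 for HTN3, 5.74 for HTN1 and 4.85 for CRYAB, and after rescaling to a common sum 5.35, 5.23 and 4.71. The common sum was larger than the deposited sums, so the pseudocount weighed less in both alternatives. The order of the 3 genes thus depended on the scale. Each was higher, or for NMRK2 lower, in both resistant libraries than in both parental libraries. All are protein-coding in GENCODE release 29 on GRCh38. CRYAB (ENSG00000109846.7_2) lies on chromosome 11 from 111908565 to 111923722 and SFRP1 (ENSG00000104332.11_3) on chromosome 8 from 41261958 to 41309497. HTN3 (ENSG00000205649.7_2) lies on chromosome 4 from 70028413 to 70036538, next to HTN1 (ENSG00000126550.8_2) from 70050402 to 70058845. TMSB4X (ENSG00000205542.10_2) lies on chromosome X from 12975108 to 12977227, and NMRK2 (ENSG00000077009.13_2) on chromosome 19 from 3933103 to 3942416.

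**Figure D1:**
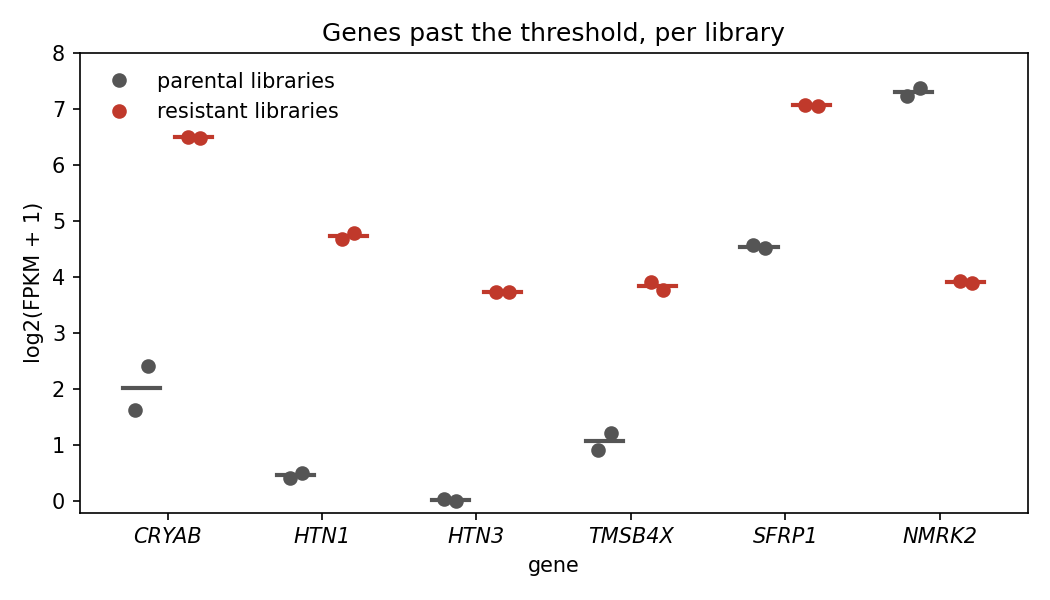
Expression of the 6 genes past the threshold, as log2(FPKM + 1) on a linear axis, in each parental library (grey points) and each resistant library (red points), with the group mean as a line. The 2 groups do not overlap for any of the 6 genes, and the replicates of CRYAB in parental libraries (2.08 and 4.31 FPKM) lie furthest apart.

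Of 10271 genes, 1667 had an unadjusted limma p under 0.05 (622 higher and 1045 lower in resistant libraries), where chance gives about 514. The balance of higher and lower genes depended on scaling, with 917 higher and 880 lower after median-of-ratios scaling and 858 higher and 943 lower after quantile normalization. Rescaling to a common sum moved it the other way, to 513 higher and 1231 lower. The groups did not overlap for 5237 genes (51.0%, against 33.3% by chance). Both chance levels are averages over comparisons. With genes that vary together, a single comparison can lie far from them. Among the 5237 genes, 151 were at least 2-fold higher and 171 at least 2-fold lower on the log2(FPKM + 1) scale. With each library rescaled to a common sum, limma called 6 genes higher and 3 lower. Without resistant replicate 1 or without resistant replicate 2, no gene was called higher (1107 and 1031 genes higher at an unadjusted limma p under 0.05), and all 6 genes missed the threshold (limma adjusted p = 0.0586 and 0.133), with a log2 fold change for CRYAB of 4.47 and 4.49. Without parental replicate 1 or parental replicate 2, limma called 17 and 19 genes higher and 13 and 11 lower. CRYAB and TMSB4X also missed the threshold with a pseudocount of 0.1 (limma adjusted p = 0.0553 and 0.0555), median-of-ratios scaling (0.0578 for both), quantile normalization (0.0571 for both) and library weights (0.0794 and 0.0713). TMSB4X missed it further with no filter (limma adjusted p = 0.0516), with the replicate number as a block (0.0758) and in the test against a fold change of 1.5 (0.0793). Adjusted p-values of CRYAB and TMSB4X ran over ranges of 4.1e-04 to 0.133 and 0.0139 to 0.133 across alternatives.

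Genes of hypoxia and glycolysis were lower in resistant cells. The list fell as a group over its 23 tested members, with a median log2 fold change of -0.65 and 22 members below 0 (limma camera adjusted p = 2.0e-06, and adjusted p = 0.81 with an estimated correlation). No member passed over all genes, and 9 fell and 0 rose when adjusted over the list alone. NDRG1, a hypoxia-induced gene, fell from 8.13 and 5.49 FPKM in the parental libraries to 0.824 and 0.715 FPKM in the resistant libraries (log2 fold change -2.12 ± 0.23 SE). BNIP3, a mitophagy receptor, fell from 29 and 28.8 to 12.6 and 13.5 FPKM. The hexokinase HK2 and the glucose transporter SLC2A1 fell by 1.01 and 1.05 on the log2 scale. The abundant glycolytic enzymes GAPDH (-0.34 ± 0.13 SE) and ENO1 (-0.18 ± 0.15 SE) did not pass. The list's median was -0.40 without resistant replicate 2.

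Targets of the transcriptional coactivators YAP and TAZ were higher in resistant cells. The list rose as a group over 14 tested members of 23 (median log2 fold change 0.55, 11 above 0, limma camera adjusted p = 3.4e-06, and adjusted p = 0.81 with an estimated correlation). Over all genes no member passed, and 6 rose and 0 fell when adjusted over the list alone. CCN1, a secreted matricellular protein, rose from 5.68 and 5.52 FPKM to 44.6 and 30.5 FPKM (log2 fold change 2.52 ± 0.23 SE). Its relative CCN2 rose from 0.989 and 0.827 FPKM to 5.85 and 4.56 FPKM. GADD45A, a stress-induced gene that is also on the p53 list, rose by this adjustment with a log2 fold change of 1.11 ± 0.26 SE.

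The 13 tested TGF-beta targets, which share CCN2 with the YAP and TAZ list, rose as a group (median log2 fold change 0.42, limma camera adjusted p = 0.00533, and adjusted p = 0.81 with an estimated correlation). None passed over all genes, and when adjusted over the list alone 5 rose, among them SMAD6 (0.77 ± 0.17 SE) and SMAD7 (0.70 ± 0.20 SE), and 1 fell, the type I receptor TGFBR1 (-1.33 ± 0.28 SE). Of 17 dedifferentiation and neural crest markers 8 were tested, and these also rose as a group (median 0.26, limma camera adjusted p = 0.00533, and adjusted p = 0.81 with an estimated correlation). Of these only NES, which encodes the intermediate filament nestin, rose when adjusted over the list alone, from 24.4 and 22.4 to 43.4 and 49.1 FPKM. The TGF-beta call was lost without resistant replicate 1 (limma camera adjusted p = 0.0908) and at a minimum mean of 5 FPKM (0.714), and the neural crest call without resistant replicate 2 (0.0978) and at that minimum (0.214).

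Genes of the NRF2 and glutathione list, which act in the defence against oxidative stress, rose as a group over 18 tested members (median log2 fold change 0.23, limma camera adjusted p = 0.00533, and adjusted p = 0.81 with an estimated correlation). In it 6 rose and 1 fell when adjusted over the list alone, and none passed over all genes. FTH1, the ferritin heavy chain, rose from 379 and 616 to 1770 and 1671 FPKM, though its many processed copies make the level uncertain. The glutamate-cysteine ligase subunit GCLM rose from 3.06 and 2.85 to 7.52 and 7.65 FPKM, and the quinone reductase NQO1 from 269 and 253 to 467 and 401 FPKM. The lipid peroxidase GPX4 went the other way, from 68.5 and 61.7 to 38.3 and 38.8 FPKM. The median was 0.33 in resistant replicate 1 and 0.06 in resistant replicate 2 against the parental mean, and without resistant replicate 1 the limma camera adjusted p was 0.0749. Without parental replicate 1 the median was 0.35.

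The 24 tested p53 targets rose as a group (median log2 fold change 0.14, 16 above 0, limma camera adjusted p = 0.00909, and adjusted p = 0.94 with an estimated correlation), and none passed over all genes. Of the members, 2 rose and 0 fell when adjusted over the list alone. The cyclin-dependent kinase inhibitor CDKN1A rose from 12.5 and 11 to 34.8 and 34.6 FPKM, and PHLDA3 from 3.41 and 3.46 to 8.93 and 9.88 FPKM. The 25 tested S phase genes fell as a group (median -0.26, 22 below 0, limma camera adjusted p = 0.025, and adjusted p = 0.979 with an estimated correlation), with 0 members past either adjustment. The helicase subunit MCM3 had a log2 fold change of -0.71 ± 0.16 SE and the replication clamp PCNA 0.12 ± 0.16 SE. The p53 call was lost without resistant replicate 1 (limma camera adjusted p = 0.14), and the S phase call without parental replicate 1 (0.102), parental replicate 2 (0.0808) or resistant replicate 2 (0.11). The p53 median was 0.08 without resistant replicate 1, 0.29 without resistant replicate 2 and 0.22 with median-of-ratios scaling, and the S phase median -0.39 without resistant replicate 1 and -0.17 with that scaling.

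The 24 tested lysosome and autophagy genes rose as a group (median 0.13, 17 above 0, limma camera adjusted p = 0.0297, and adjusted p = 0.979 with an estimated correlation), with 0 members past either adjustment. NPC2, a cholesterol transfer protein, stood at 0.54 ± 0.15 SE and the protease CTSL at -1.25 ± 0.26 SE on the log2 scale. This call was lost without parental replicate 2 (limma camera adjusted p = 0.285), resistant replicate 1 (0.11) or resistant replicate 2 (0.0555), and at a minimum mean of 5 FPKM (0.0562). The median was 0.20 without parental replicate 1, 0.22 without resistant replicate 2, 0.23 with median-of-ratios scaling and 0.22 with quantile normalization.

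**Figure D2:**
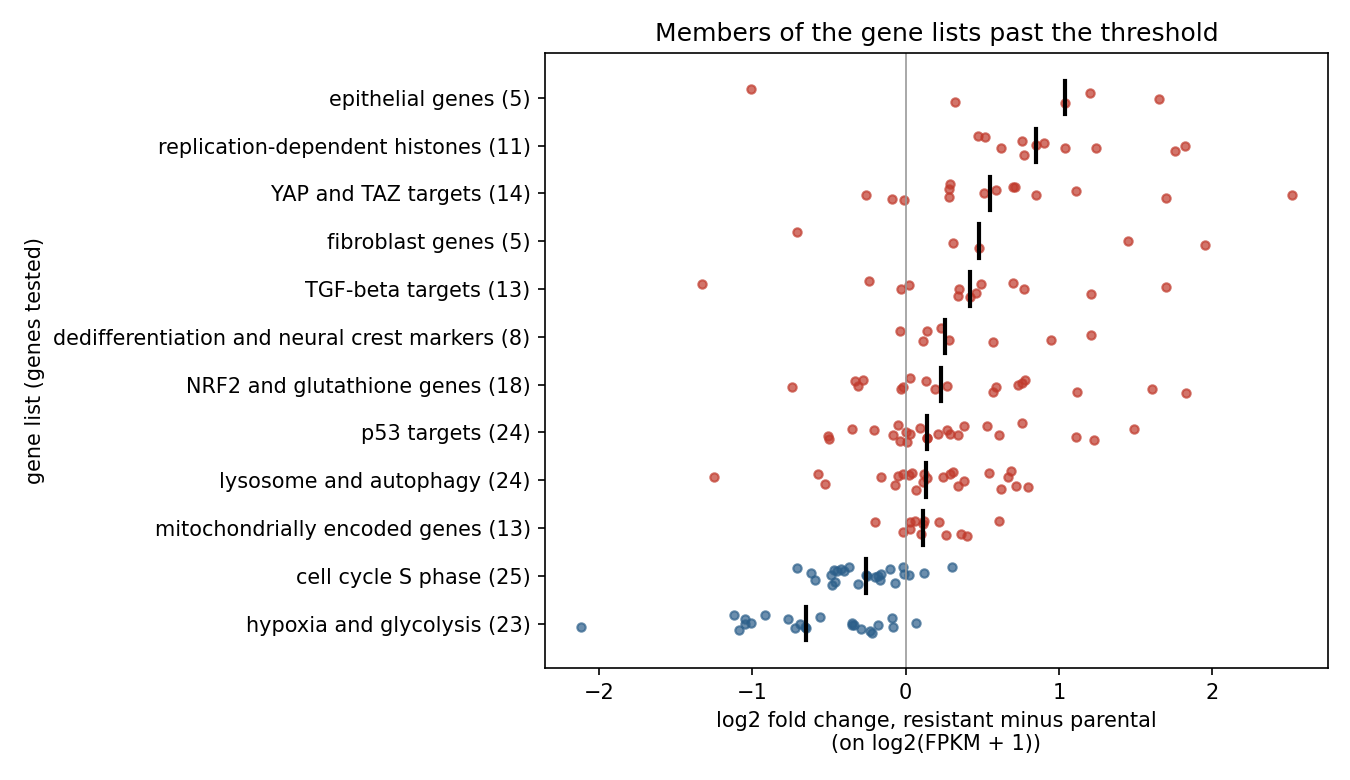
Log2 fold changes (resistant minus parental, on the log2(FPKM + 1) scale) of the tested members of the 12 gene lists past the camera threshold, with 1 point per gene, red for lists higher and blue for lists lower in resistant libraries, and the list's median as a black line. The hypoxia and glycolysis list has the lowest median (-0.65) and the epithelial list the highest (1.04, from 5 genes).

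Markers of other cell types moved in both directions. Of 19 epithelial genes on the list only 5 were tested, and these rose as a group (median 1.04, limma camera adjusted p = 0.0374, and adjusted p = 0.81 with an estimated correlation). None passed over all genes, and when adjusted over the list alone the keratins KRT8 (0.252 and 0.364 to 1.56 and 1.84 FPKM), KRT18 (2.67 and 3.26 to 6.73 and 9.62 FPKM) and KRT19 (0.205 and 0.287 to 1.1 and 6.29 FPKM) rose, and the cadherin CDH3 fell (2.55 and 2.11 to 0.759 and 0.551 FPKM). KRT8 and KRT19 lay under 1 FPKM in both parental libraries, so they could pass the filter only through the resistant ones. Of 13 fibroblast genes on the list only 5 were tested, and these rose as a group (median 0.48, limma camera adjusted p = 0.025, and adjusted p = 0.81 with an estimated correlation). Of these, S100A4 rose from 0.83 and 1.56 to 7.3 and 7.46 FPKM and ACTA2 from 0.741 and 0.891 to 4.78 and 3.28 FPKM when adjusted over the list alone, and FBLN1 fell from 26.1 and 23.3 to 15.4 and 14 FPKM. The leukocyte list had 2 tested members and no set test, and CD68 (-1.45 ± 0.25 SE) and LCP1 (-0.89 ± 0.17 SE) fell when adjusted over it alone. Endothelial genes (3 tested, limma camera adjusted p = 0.949) and retinal pigment epithelium genes (3 tested, adjusted p = 0.359) did not pass. The pigment epithelium list passed in the lower direction without parental replicate 2 (limma camera adjusted p = 0.0267), and its median of -0.29 was -0.08 without parental replicate 1, -0.95 without parental replicate 2 and -0.54 without resistant replicate 1. The epithelial call was lost without parental replicate 1 (limma camera adjusted p = 0.0526) or resistant replicate 2 (0.0978) and with median-of-ratios (0.128) or quantile (0.135) scaling. The fibroblast call was lost without resistant replicate 1 (0.109) or resistant replicate 2 (0.0978) and with those scalings (0.0603 and 0.0546).

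Among the library checks, replication-dependent histone genes rose as a group (11 tested of 21 on the list, median log2 fold change 0.85, 11 above 0, limma camera adjusted p = 9.0e-09, and adjusted p = 0.81 with an estimated correlation). Of these, 9 rose and 0 fell when adjusted over the list alone and 0 passed over all genes, among them H2BC12 (44.1 and 52.8 to 159 and 83.4 FPKM) and H4C3 (28.8 and 39.2 to 53.5 and 70.5 FPKM). Histone genes form a multigene family, so single members are uncertain. Mitochondrially encoded genes took 37.2% and 37.9% of FPKM in parental and 40.2% and 40.6% in resistant libraries. That list rose as a group (13 tested, median 0.11, limma camera adjusted p = 0.00909, and adjusted p = 0.81 with an estimated correlation), with 0 members past either adjustment, MT-ATP6 at 0.26 ± 0.10 SE and MT-CO2 at -0.20 ± 0.10 SE. Under quantile normalization its direction turned (adjusted p = 0.949), and the call was lost without resistant replicate 1 (limma camera adjusted p = 0.0774), resistant replicate 2 (0.0978) or the variance trend (0.0586). The median was 0.20 without resistant replicate 2, 0.21 with median-of-ratios scaling, 0.06 after rescaling to a common sum and 0.00 with quantile normalization. Cytosolic ribosomal protein genes (35 tested, adjusted p = 0.802) and immediate early genes (12 tested, adjusted p = 0.235) did not pass limma camera. Without resistant replicate 1 the ribosomal protein list passed in the higher direction (limma camera adjusted p = 0.0348, median 0.05, against a median of -0.01 with all libraries).

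The pigment cell identity genes stayed expressed. In parental and resistant libraries respectively, PMEL stood at 500 ± 170 and 366 ± 40.1 FPKM, MLANA at 216 ± 7.47 and 210 ± 3.3, TYR at 117 ± 5.62 and 146 ± 44.4, SOX10 at 82.5 ± 13.1 and 54.6 ± 0.417, and MITF at 36.4 ± 1.49 and 20.7 ± 15.7 (SD, n = 2 each). None of these passed over all genes (limma adjusted p from 0.228 for SOX10 to 0.884 for MLANA). MITF, the lineage transcription factor, stood at 9.64 FPKM in resistant replicate 1 and 31.8 FPKM in resistant replicate 2. The melanocyte lineage list as a whole did not pass (23 tested, limma camera adjusted p = 0.37), and adjusted over the list alone 2 members rose and 3 fell. The melanin enzyme DCT fell from 4.88 and 5.46 to 0.486 and 0.517 FPKM, and CAPN3 (-1.28 ± 0.22 SE) and IRF4 (-0.99 ± 0.19 SE) fell. CDH19 rose from 4.92 and 4.7 to 17.8 and 15.8 FPKM, and the endothelin receptor EDNRB rose by this adjustment (0.87 ± 0.16 SE).

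The uveal melanoma genes GNAQ (12.5 ± 0.173 and 12.1 ± 0.623 FPKM), GNA11 (5.77 ± 0.182 and 7.42 ± 1.58), BAP1 (4.69 ± 0.214 and 4.15 ± 0.175), SF3B1 (23.9 ± 0.493 and 21.2 ± 8.48) and EIF1AX (59.2 ± 1.94 and 61.4 ± 5.08) did not pass over all genes between parental and resistant libraries (SD, n = 2 each, limma adjusted p from 0.513 to 0.916). Their list did not pass (17 tested, limma camera adjusted p = 0.949). Adjusted over the list alone, only the leukotriene receptor CYSLTR2 rose, from 0.0744 and 0.0818 to 3.03 and 1.83 FPKM.

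Other fixed lists did not pass limma camera. The adjusted p was 0.583 for oxidative phosphorylation (33 tested, 3 higher and 0 lower when adjusted over the list alone), 0.408 for WNT targets, 0.787 and 0.949 for class 1 and class 2 classifier genes, 0.847 for interferon-stimulated genes, cholesterol synthesis and the unfolded protein response, and 0.863 for checkpoint ligands and tumour antigens. It was 0.913 for epigenetic regulators, 0.949 for antigen presentation, NOTCH targets and the integrated stress response, and 0.992 for BCL2 family genes and PI3K, AKT and FOXO genes. For oxidative phosphorylation camera's direction was up and the mean log2 fold change 0.02, while the median was -0.05. The direction was also up with a median below 0 for the interferon, checkpoint, unfolded protein, stress response, BCL2, epigenetic, ribosomal protein and endothelial lists. Their mean log2 fold changes were 0.02, -0.01, 0.01, -0.06, -0.06, 0.00, 0.01 and 0.00 in that order, so mean and median differed in sign for the interferon, unfolded protein and ribosomal protein lists.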

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

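Robust variance moderation, library weights, leaving out the mitochondrially encoded genes and a threshold of 0.1 were chosen after seeing the data. Genes called higher in resistant libraries (5) numbered 3 with a pseudocount of 0.1, 3 with median-of-ratios scaling, 3 with quantile normalization, 3 with library weights and 45 at an adjusted p under 0.1, and ran from 0 to 19 with 1 library left out. Genes called lower (1) numbered 3 after rescaling to a common sum (adding DCT and ZNF284, while DAG1 was added higher), 5 with robust variance moderation (adding DCT, CPM, MTURN and ZNF284, while BCAT1 and DAG1 were added higher) and 38 at an adjusted p under 0.1, and ran from 0 to 13 with 1 library left out. Without resistant replicate 2, limma called 0 genes lower, with 1164 lower at an unadjusted p under 0.05. Without resistant replicate 1, the gene called lower was BLOC1S5-TXNDC5, not NMRK2. Leaving out a library leaves 1 residual degree of freedom. These genes outside the rule were named after their values were seen.

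NMRK2, SFRP1, HTN1 and HTN3 passed in 14 of 16 alternatives, CRYAB in 10 and TMSB4X in 7, always in the same direction. CRYAB had an adjusted p from 4.1e-04 to 0.133 and TMSB4X from 0.0139 to 0.133. Gene lists called higher (10) numbered 5 at a minimum mean of 5 FPKM and 0 with an estimated correlation (2 at an unadjusted p under 0.05), and ran from 5 to 9 with 1 library left out. Lists called lower (2) numbered 0 with an estimated correlation (0 at an unadjusted p under 0.05) and ran from 1 to 2 with 1 library left out. Histone, hypoxia and YAP and TAZ lists passed in every alternative run except the estimated correlation. Shifted chromosomes (2) numbered 0 with an estimated correlation (0 at an unadjusted p under 0.05) and 3 at a minimum mean of 5 FPKM, and ran from 0 to 2 with 1 library left out. The cause was not tested.

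Replicate numbers in the labels share only a number: same-numbered libraries deviated from their group means with a correlation of -0.071 across genes. With the replicate number as a block, limma called 4 genes higher and 1 lower, leaving out TMSB4X (adjusted p = 0.0758), and camera 10 lists higher, 2 lower and 2 chromosomes. The 4 libraries allow 3 splits into 2 and 2, too few for a share under 0.05. The real split gave 6 calls and the highest other split 3. Each group of the other splits mixes a parental and a resistant library, so any difference between the real groups widens the spread there. Fewer calls in those splits are thus built in and do not measure chance.

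Small changes turned sign, none of them past the threshold: MLANA with median-of-ratios scaling (0.06), GNAQ with median-of-ratios scaling (0.05), with quantile normalization (0.06) and without resistant replicate 1 (0.01, against -0.09 without resistant replicate 2), TYR without resistant replicate 1 (-0.03, against 0.60 without resistant replicate 2), SF3B1 without resistant replicate 2 (0.18, against -0.62 without resistant replicate 1), EIF1AX after rescaling to a common sum (0.00) and without resistant replicate 2 (-0.03, against 0.13 without resistant replicate 1), PCNA without resistant replicate 1 (-0.05, against 0.28 without resistant replicate 2) and TYRP1 with quantile normalization (-0.17). The list of mitochondrially encoded genes turned with quantile normalization (adjusted p = 0.949).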

Other observations

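The tests of S phase genes and of readthrough genes, the use of an SE for MT-ND6 and the windows along chromosomes were chosen after the values they measure had been seen.

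Several lists did not pass limma camera, yet held single members that passed an adjustment over the list alone. None of these members passed over all genes (limma adjusted p = 0.0781 for CD36 and 0.131 for ABCB5). The adjustment over a list alone was not corrected for the number of lists. In the fatty acid list (17 tested, limma camera adjusted p = 0.847), the fatty acid transporter CD36 rose from 13.6 and 14.9 to 75.1 and 52.5 FPKM and the carnitine palmitoyltransferase CPT1A from 4.11 and 3.47 to 10.6 and 9.21 FPKM, while the desaturase SCD fell from 119 and 118 to 57.1 and 36.3 FPKM, and LPL (-0.83) and SREBF1 (-0.80) fell on the log2 scale. Among 16 receptor tyrosine kinases and ligands (limma camera adjusted p = 0.949), ERBB3 rose from 3.13 and 3.57 to 8.81 and 13 FPKM and PDGFB from 3.98 and 3.22 to 8.41 and 9 FPKM, and VEGFC fell from 7.73 and 7.15 to 4.01 and 3.84 FPKM. Of 9 drug efflux transporters (limma camera adjusted p = 0.949), ABCB5 rose from 2.36 and 2.15 to 7.4 and 5.45 FPKM, and ABCC11 (-1.23) and ABCA3 (-0.97) fell on the log2 scale.

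The MAPK output list went both ways (17 tested, limma camera adjusted p = 0.949). When adjusted over the list alone, DUSP6 (1.00) and FOSL1 (0.56) rose, and PHLDA1 (-0.93), ETV4 (-0.78) and MYC (-0.91) fell on the log2 scale. The mesenchymal list also went both ways (16 tested, adjusted p = 0.992): S100A4 and FN1 rose (FN1 from 1.12 and 1.25 to 9.02 and 5.12 FPKM), and VIM (-0.53), LOX (-0.68) and ITGA5 (-0.69) fell. The chemokine CXCL8 rose from 0.834 and 1.42 to 5.37 and 5.71 FPKM in a list of NF-kappaB genes that did not pass (8 tested, adjusted p = 0.847). In the kinase, mesenchymal and NF-kappaB lists camera's direction was up while the median log2 fold change lay below 0 (-0.14, -0.12 and -0.11). Among G2 and M phase genes (30 tested, limma camera adjusted p = 0.108), only the kinase AURKB fell when adjusted over the list alone, from 25 and 20.4 to 9.22 and 6.91 FPKM.

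Histone genes were higher in both resistant libraries, with a median of 0.76 and 0.99 on the log2 scale above the parental mean, against 0.07 between the parental libraries. A gain common to transcripts of similar length is argued against. Of 10000 gene lists matched on exon length and mean FPKM, 0.00% reached the histone median of 0.85 (median of the matched lists -0.03). Matching was in 10 bins of each, so a gain confined to the very shortest transcripts stays open. The S phase genes gave no sign of a larger share of cells in S phase. Their median log2 fold change was -0.26 (95% bootstrap interval -0.45 to -0.16 over 25 genes). That explanation is not excluded, since the test was chosen after these values were seen. The S phase list also did not pass with an estimated correlation (limma camera adjusted p = 0.979). Less complete poly(A) selection, which could raise transcripts without a tail, stays open. MT-ND6, a mitochondrial mRNA without a poly(A) tail, changed by 0.13 less than the other mitochondrially encoded genes (a difference of -0.13, SE 0.19), but it is 1 gene, and resistance itself stays open and untested.

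Genes annotated as readthroughs of a pair of neighbours swung between libraries of 1 group, with a median replicate SD of 0.53 on the log2 scale over 26 genes, which 0.00% of 10000 lists matched on mean FPKM reached (median 0.19). BLOC1S5-TXNDC5 stood at 141 and 141 FPKM in parental and at 96.7 and 0.102 FPKM in resistant libraries, while TXNDC5, which it overlaps, stood at 4.21, 5.71, 9.39 and 54.4 FPKM. Their sum was 145 and 147 FPKM in parental and 106 and 54.5 FPKM in resistant libraries, that of RPL17-C18orf32 and RPL17 was 295, 316, 244 and 220 FPKM, and that of PEDS1-UBE2V1 (listed at 0, 26.1, 14.3 and listed at 0) and UBE2V1 was 48, 56.9, 48.6 and 38.7 FPKM. Reads assigned back and forth between overlapping gene models stay open as an explanation, since the swings themselves prompted this test and the sums, examined after they were seen, moved less between the resistant libraries than the readthrough gene did in these 3 pairs, but were 106 and 54.5 FPKM there for the first pair. No biological explanation was tested, and fold changes of such genes are not reported as changes.

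Chromosome 2 genes were higher and chromosome 9 genes lower in resistant libraries (663 and 426 genes, limma camera adjusted p = 8.1e-04 and 0.00604, and adjusted p = 0.981 for both with an estimated correlation). The median differed from the other chromosomes by 0.16 (95% bootstrap interval over genes 0.13 to 0.20) and -0.14 (-0.17 to -0.09). In the 2 resistant libraries it differed by 0.18 and 0.15 (chromosome 2) and by -0.14 and -0.13 (chromosome 9). The intervals leave out the spread between libraries. Gene length and expression alone did not account for these medians, since 0.00% of 10000 matched lists reached that of chromosome 2, and 0.00% that of chromosome 9. The share was also 0.00% for chromosomes 1, 4, 12 and 19, 0.03% for chromosome 11 and 0.12% for chromosome 8, which camera did not call. Medians of so many genes vary little between draws, so these shares cannot exclude a part played by length or expression. A change in copy number, of the whole chromosome, a part of it or a part of the cells, stays open. Both intervals lie inside 0.26, the smallest shift set beforehand as a sign of a whole copy in most cells. That bound was a fraction of 1 copy in a diploid line, not the full shift of a copy. It assumed a diploid line, and the ploidy was not measured. Both calls were lost without parental replicate 1 (limma camera adjusted p = 0.0678 for both) or resistant replicate 1 (0.0612 and 0.118).

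In windows of about 60 genes, all 11 windows of chromosome 2 lay above the median of all genes and all 7 windows of chromosome 9 below it. In both resistant libraries taken singly, 10 of the 11 windows of chromosome 2 lay above it, and the window from 203394345 to 223967714 stood at 0.00 in resistant replicate 2. The highest window of chromosome 2 ran from 26034107 to 37324808 (0.27). The lowest of all 169 windows, at -0.27, ran from 53285 to 16898809 on chromosome 4, where the parental libraries differed by -0.07 (replicate 2 minus 1). On chromosome 6 the windows from 30541377 to 32844703 and from 32844136 to 38154624 lay at -0.25 and -0.24, and on chromosome 8 those from 406428 to 26372680 and from 26382898 to 42897290 at -0.21 and -0.25. The parental libraries (replicate 2 minus 1) differed by -0.13 and -0.07 in these windows of chromosome 6, and by -0.03 and 0.03 in those of chromosome 8. On chromosome 9 the windows from 128305161 to 133351426 and from 133351755 to 137870016 lay at -0.21 and -0.23. There too the parental libraries differed (replicate 2 minus 1, -0.12 and -0.18), and the second window stood at -0.33 and -0.14 in the resistant libraries.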
